A study of Mus musculus with 6 samples.

How the data were processed

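RNA of bone marrow stromal cells from male C57BL/6 mice was sequenced in 6 libraries, 3 labelled shControl and 3 labelled shVdac, per the labels from 1 ug of total RNA and with paired reads of 150 bp. The values were FPKM (fragments scaled by gene length and library depth) per the file headers, 1 column per library, rounded by the authors to 2 decimals. The submitters' processing notes name cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1, DESeq2 1.30.1 and the mouse build GRCm39, without their roles or order. The annotation, the gene lengths and the total used for library depth are not given in the sources used here, nor is whether strand was used in counting, so reads of overlapping genes, antisense genes and near-identical copies may be shared. No coordinates were used.

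The table had 56691 rows, of which 2639 had no gene symbol. Rows without a symbol were left out, 1 row was kept for each repeated symbol, and 53170 symbols remained, of which 50559 had an exon length in GENCODE M21. No 2 columns were identical, and 0 value columns lacked a sample. The depth was recovered from the values: among genes with exons shorter than 400 bp, low FPKM lie on steps of 1 fragment, and 95.7% to 97.0% of the values checked lay within 0.15 of a whole number of fragments. This gave about 16100000 to 17700000 fragments per library, and the fragments summed over genes came to 98.2% to 98.3% of that total. Counting errors and the variance between libraries were taken from these fragments, and cover counting only.

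The comparison was between the libraries labelled shVdac and those labelled shControl, with the label as the only term. Genes with at least 1 FPKM in at least 3 libraries were tested on log2(FPKM + 1), without further scaling, with limma 3.58.1 in R 4.3.3 (empirical Bayes moderation with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method over all tested genes at 0.05. Vdac1 and the other genes always named were also tested with an exact two-sided permutation test. Gene lists, 32 in number, were tested with camera of limma at a correlation of 0.01 where at least 5 members were tested, with p-values adjusted over the 30 lists that qualified. Beside this, camera with an estimated correlation, and fry of limma, which asks whether the genes of a list move one way on balance, were run. Of 743 list entries, 1 was not in the table and 4 were matched under an older symbol.

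The lists, the tests of genes and lists between the labels, the alternatives except the 2 named below as added, and the rule for naming genes were chosen before the data were examined. Several tests of explanations were chosen later, as named with them. The rule took 12 genes always named; in each direction the 10 with the largest log2 change among those past adjusted p of 0.05 whose libraries did not overlap between groups, leaving out predicted or unnamed genes; and up to 4 members of each list with the smallest p. Alternatives were a pseudocount of 0.1, no filter on low values, a minimum of 5 FPKM, rescaling of each library to the same sum (TPM), median-ratio scaling, quantile normalization, no intensity trend, robust moderation, array weights, a replicate block, an adjusted p of 0.01, and leaving out each of the 6 libraries in turn. Limma voom on recovered fragments, and leaving out each library while keeping the genes tested on all 6, were added after seeing the data. The latter was added because the filter asks for 3 libraries, and with 2 libraries of a label left, genes expressed under that label alone no longer pass it. Copies of the Vdac1 transcript were searched with BLAST 2.17.0 at 90% identity over at least 150 bp in the GENCODE M21 transcripts. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

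The steps were tested on simulated data for the comparison of shVdac with shControl. With 200 genes changed by a log2 value of 0.25, 3.57% of the 196 tested were recovered; at 0.5, 84.9% of 192; and at 1, 95.8% of 193, with 1, 9 and 19 false calls among about 12066 genes. With no change simulated, 0 genes were called. A simulated shift of the glycolysis list was called up, and 1 other list was called with it. The simulation used a CV of 3% between libraries beyond counting error, and far fewer changed genes than the 7877 called in the data. Its recovery and false calls therefore do not give the sensitivity of the real comparison, nor do they cover variation between mice or cultures.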

Results

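RNA from mouse bone marrow stromal cells (called mesenchymal stem cells by the submitters, adherent marrow cells that can form bone, fat and cartilage) was sequenced in 6 libraries. The cells came from young male C57BL/6 mice, 4 weeks of age. The 3 libraries labelled shControl were the controls for short hairpin RNA, and the 3 libraries labelled shVdac carried, per the labels, a knockdown of Vdac, which the study's design text names as Vdac1, the main voltage-dependent anion channel of the outer mitochondrial membrane. The study's title links the innate immune adaptor STING, Hk2 and Vdac1 to bone loss with age, and the comparison asks which transcripts differ under the hairpin. Values were FPKM (fragments scaled by gene length and library depth) as the authors deposited them, and the steps between low values put the depth at about 16100000 to 17700000 fragments per library. Between 11977 and 12404 rows reached 1 FPKM in a library, and the 10 highest genes took 11.2% to 11.4% of the summed FPKM in the shControl libraries and 13.2% in the libraries labelled shVdac.

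Vdac1, the targeted gene, was not lower in the libraries labelled shVdac. Its FPKM was 97.8, 92.6 and 92.2 in shControl replicates 1, 2 and 3, and 101, 105 and 108 in the libraries labelled shVdac. The means were 94.2 ± 3.13 and 105 ± 3.42 FPKM (SD, n = 3 each), a log2 difference of 0.16 (SE 0.037, limma adjusted p = 0.00642), which is 1.12 times the shControl mean. The exact two-sided permutation test over the 3 against 3 assignments gave p = 0.1, the smallest value this design allows. The 95% interval of the ratio on the log2(FPKM + 1) scale ran from 1.05 to 1.18, so a lower Vdac1 transcript level lay outside it. About 4198 and 4638 fragments per library stood behind the means, with a counting error of 1.5%. The transcript level therefore goes against the label, and every direction given here is between libraries by their labels, not between cells shown to have more and less Vdac1 transcript. Vdac2 and Vdac3, the other channel genes of the family, fell from 61.7 ± 1.56 to 54.5 ± 1.94 FPKM (log2 change -0.18, adjusted p = 0.0032) and from 17.5 ± 0.194 to 15.3 ± 0.68 FPKM (log2 change -0.18, adjusted p = 0.00586). With each library scaled by its median ratio, these changes were -0.06 and -0.07 and did not pass the test. Vdac3 values are uncertain, because a pseudogene of it was listed at 51.2 ± 3.5 and 46.7 ± 3.79 FPKM, above the gene itself, and reads may have been split between them.

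**Figure D1:**
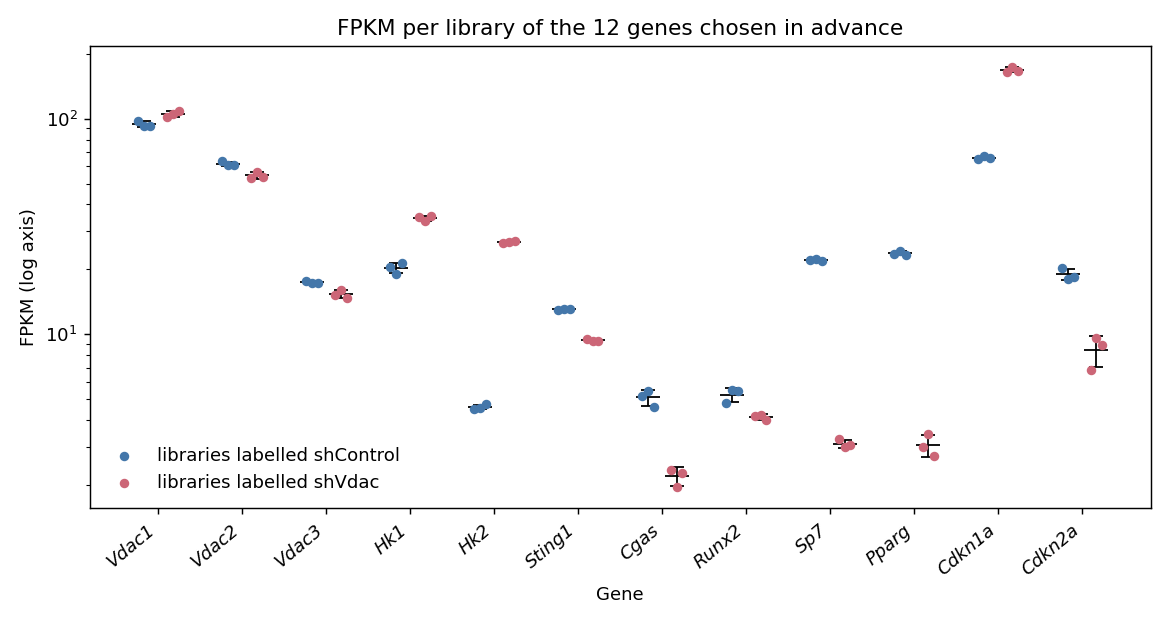
FPKM on a log axis for the 12 genes chosen before the data were examined; each point is 1 library (3 labelled shControl, 3 labelled shVdac) and bars give the mean ± SD. Vdac1 lay at 94.2 and 105 FPKM, Hk2 rose from 4.6 to 26.8 FPKM, and Sp7 and Pparg fell to 3.11 and 3.06 FPKM in the libraries labelled shVdac.

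The libraries with the 2 labels differed widely in their transcripts. On the log2(FPKM + 1) scale, Cxcl3, Saa3, Lcn2 and Arg1 rose furthest in the libraries labelled shVdac, and Pcp4l1, Lpl and Ccnb2 fell furthest. Of 12491 genes tested, 2879 were higher and 4998 lower in the libraries labelled shVdac at a limma adjusted p under 0.05. At least 2-fold changes were seen in 560 of the higher and 789 of the lower genes. Without shControl replicate 1, 2 or 3 these counts were 565 and 513, 572 and 500, and 569 and 503, since genes seen in the shControl libraries alone then no longer reached 1 FPKM in 3 libraries; with the same genes tested they were 567 and 799, 573 and 790, and 570 and 791. The first principal component held 93.2% of the variance and separated the labels. The libraries of the groups did not overlap for 8494 genes, 68% of those tested, where chance gives 10%. Exchanges of libraries between groups cannot give an exact permutation p under 0.1 for any single gene. The split of calls depends on how libraries are scaled to each other: 36.6% of changed genes were higher without further scaling, 50.9% with median-ratio scaling and 48.4% with quantile normalization, which moved the log2 change of a typical gene by 0.1 and 0.083. Small changes therefore have a direction only relative to the scaling.

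On the same scale, the 10 largest rises in the libraries labelled shVdac began with Cxcl3, a neutrophil-attracting chemokine, which went from 0.11 ± 0.0436 to 382 ± 12.5 FPKM (log2 change 8.43, SE 0.043). Saa3, an acute-phase serum amyloid, went from 17.1 ± 0.312 to 2675 ± 179 FPKM. Lcn2, the iron-sequestering protein lipocalin 2, reached 207 ± 4.64 FPKM from 0.527 ± 0.0252, and Arg1, an arginase of alternatively activated macrophages, reached 142 ± 0.506 FPKM from 0.127 ± 0.0416. The interleukin 1 genes Il1a and Il1b stood at 141 ± 3.46 and 94.5 ± 4.52 FPKM, against 0.303 and 0.0733 FPKM in the shControl libraries. The matrix protease gene Mmp3 and the chemokine genes Ccl5, Cxcl5 and Cxcl1 completed this set, with log2 changes of 6.64, 6.51, 6.46 and 6.36. The 10 largest falls began with Pcp4l1 (49.2 ± 2.6 to 0.957 ± 0.381 FPKM, log2 change -4.70). Lpl, lipoprotein lipase, went from 291 ± 5.67 to 11.2 ± 0.0902 FPKM, and Bmp4, a bone-inducing growth factor, went from 57.8 ± 1.67 to 2.46 ± 0.445 FPKM. Car3, a carbonic anhydrase abundant in fat cells, went from 15 ± 0.609 to 0.08 ± 0.02 FPKM. The other 6 genes, Ccnb2, Pbk, Ccna2, Top2a, Plk1 and Stmn1, belong to cell division, and their log2 changes lay between -4.58 and -3.70. The limma adjusted p of these 20 genes was at most 2.5e-08. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes near 0, so ratios of mean FPKM order these genes otherwise.

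**Figure D2:**
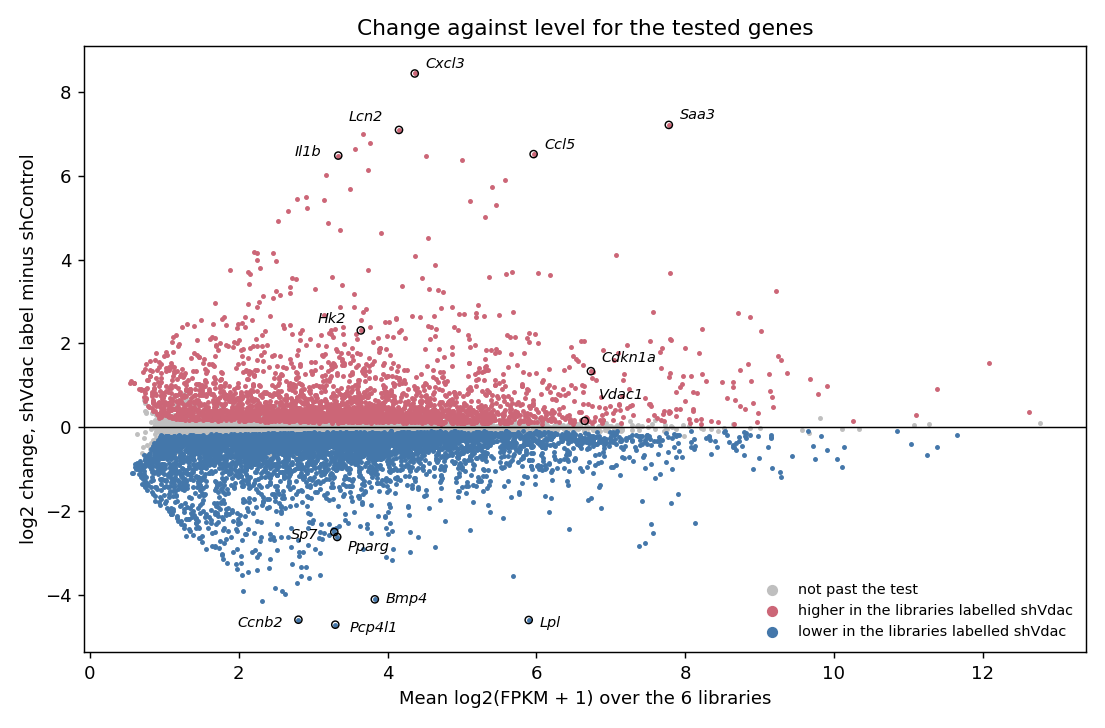
Each point is 1 of the 12491 tested genes, with its mean log2(FPKM + 1) over the 6 libraries on the x axis and its log2 change on the y axis; red genes were higher and blue genes lower in the libraries labelled shVdac at adjusted p under 0.05. The rises reach 8.43 (Cxcl3) and the falls -4.70 (Pcp4l1), while Vdac1 lies at 0.16.

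Genes of glucose uptake and glycolysis rose together in the libraries labelled shVdac. Hk2, the inducible hexokinase that binds the outer mitochondrial membrane, went from 4.6 ± 0.115 to 26.8 ± 0.271 FPKM, 5.82-fold (log2 change 2.31, SE 0.037, adjusted p = 1.37e-09). Hk1, the constitutive hexokinase, went from 20.3 ± 1.13 to 34.6 ± 0.909 FPKM, 1.7-fold (adjusted p = 2.5e-06). Of 21 glycolysis genes, 20 rose and 1 fell, with the same counts adjusted over the list alone, and 11 rose at least 2-fold (median log2 change 1.05, camera adjusted p = 6.88e-13; adjusted p = 0.0434 with an estimated correlation). The lactate exporter gene Slc16a3 rose 6.56-fold to 90.1 ± 1.17 FPKM, the glucose transporter gene Slc2a1 rose 4.76-fold to 104 ± 1.04 FPKM, and Pfkfb3, whose product makes an activator of phosphofructokinase, rose 6.52-fold to 36.3 ± 1.29 FPKM. The member that fell was the glucose transporter gene Slc2a3 (log2 change -0.64). Gapdh was listed at only 4.04 and 12.1 FPKM, far below Pkm at 416 and 757 FPKM, and is uncertain because reads may be shared with its near-identical copies. Of 20 genes of the hypoxia response, 18 rose and 1 fell, also adjusted over the list alone (median log2 change 1.32, camera adjusted p = 4.43e-12; adjusted p = 0.0108 with an estimated correlation). Vegfa, the vascular growth factor, rose 3.03-fold to 163 ± 1.99 FPKM, Bnip3, a mitophagy receptor, rose 3.81-fold to 170 ± 1.75 FPKM, and Egln3, an oxygen-sensing hydroxylase, rose 9.52-fold to 26.7 ± 0.342 FPKM. Ndrg1 fell (log2 change -0.64). The hypoxia list shares 4 of its members with other lists, among them Slc2a1 and Pfkfb3 with glycolysis.

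Nuclear genes of mitochondrial respiration differed little between the labels, and 9 of 13 transcripts of the mitochondrial genome were lower in the libraries labelled shVdac. Of 73 genes of the respiratory chain and ATP synthase, 11 rose and 15 fell (8 and 12 adjusted over the list alone) and none reached 2-fold; their median log2 change was 0.01 with an SD of 0.18, and the list was not called (camera adjusted p = 0.327). Those with the smallest p were Cox7a2l, Atp5a1, Ndufs8 and Ndufb11, whose log2 changes lay between -0.47 and -0.23. Of the 13 transcripts of the mitochondrial genome, 9 fell and 4 did not pass (1 rose and 10 fell adjusted over the list alone), with a median log2 change of -0.43 (camera adjusted p = 0.0448; adjusted p = 0.206 with an estimated correlation). mt-Nd2 went from 1364 ± 38 to 813 ± 15.2 FPKM, and mt-Nd1, mt-Cytb and mt-Nd4, like it parts of the respiratory complexes, fell by 0.40, 0.46 and 0.43 on the log2 scale. mt-Co1, the highest of them, stood at 6736 ± 136 and 7236 ± 343 FPKM (adjusted p = 0.057). Values of this list are uncertain, since mt-Co3 was listed at 14.7 FPKM beside mt-Co1, and reads may be shared with nuclear copies of mitochondrial DNA. The call was lost without shVdac replicate 1 (adjusted p = 0.0545), without shVdac replicate 3 (0.0553), with genes of at least 5 FPKM only (0.0567) and without the intensity trend (0.0669), with a range of 0.00505 to 0.0669 over 17 alternatives. With the same genes tested it was lost without shControl replicate 1 or 3 instead (0.0593 and 0.0588). Of 21 genes of the tricarboxylic acid cycle, 3 rose and 12 fell, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.262) except without a filter on low values (0.0471, in a range of 0.0471 to 0.579 over 17 alternatives). Idh2, the mitochondrial isocitrate dehydrogenase, fell from 39.2 ± 1.22 to 16.6 ± 0.359 FPKM, as did Suclg2 and Idh3g (log2 changes -0.45 and -0.38), while Mdh2 rose (0.56). Of 18 genes of a list that holds Vdac2, Vdac3 and partners of VDAC in the outer membrane and permeability pore, but not Vdac1, 6 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.275). Besides both hexokinases, Tspo, the translocator protein of the outer membrane, rose 1.72-fold to 109 ± 9.58 FPKM and Hspa9, a mitochondrial chaperone, rose 1.24-fold. Of 20 genes of mitochondrial dynamics and mitophagy, 4 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.873). Here Bnip3 and Sqstm1 rose, and Pink1, the kinase that marks damaged mitochondria, and Optn, an autophagy receptor, fell (log2 changes -0.64 and -0.78).

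Genes induced by interferon rose in the libraries labelled shVdac, while the sensor and adaptor of cytosolic DNA fell. Sting1, which encodes STING, went from 13.1 ± 0.0902 to 9.36 ± 0.139 FPKM (log2 change -0.44, SE 0.036, adjusted p = 1.41e-05). Cgas, the DNA sensor upstream of it, went from 5.09 ± 0.44 to 2.2 ± 0.217 FPKM (log2 change -0.93, adjusted p = 1.48e-05). Of 40 interferon-stimulated genes, 39 rose, 27 of them at least 2-fold (median log2 change 1.32, camera adjusted p = 2.61e-22; adjusted p = 0.00603 with an estimated correlation). Adjusted over the list alone, 39 rose and 1 fell. Irf7, the transcription factor that amplifies interferon production, rose 10.8-fold to 78.3 ± 0.271 FPKM. Ifit1, an antiviral RNA-binding protein, rose 11.2-fold to 72.5 ± 0.669 FPKM, Usp18, a protease that removes ISG15, rose 9.27-fold, and Rtp4 rose 5.31-fold. The exception was Gbp2, at 39.7 ± 1.93 and 36.9 FPKM (adjusted p = 0.0722). Of 16 genes of the cGAS-STING pathway, 8 rose and 6 fell, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.158). Besides Irf7, the nucleic acid sensor gene Zbp1 rose 14.6-fold and the kinase gene Ikbke 2.18-fold, while Samhd1, a nucleotide hydrolase that limits cytosolic DNA, fell (log2 change -0.91). The pathway list was called with genes of at least 5 FPKM only (adjusted p = 0.0405) and with voom on recovered fragments (0.0444), in a range of 0.0405 to 0.314 over 17 alternatives, and had an adjusted p = 0.609 with an estimated correlation. Ifnb1, interferon beta, was listed at 0 in each shControl library and at 0.33, 0.24 and 0.08 FPKM in the libraries labelled shVdac, too low to be tested.

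Most inflammatory and secretory factors were higher in the libraries labelled shVdac. Of 30 tested, 24 rose and 2 fell, also adjusted over the list alone, and 23 rose at least 2-fold (median log2 change 3.17, camera adjusted p = 6.43e-17; adjusted p = 0.00606 with an estimated correlation). Without shVdac replicate 1, 2 or 3 the median was 1.92, 1.97 and 1.92, over the 21 members that then reached 1 FPKM in 3 libraries, and with the same 30 members tested it was 3.18, 3.18 and 3.16. Cxcl1, Lcn2, Saa3 and Mmp3 had the smallest p. The 2 that fell, Igfbp4 and Igfbp5, encode binding proteins of insulin-like growth factors (445 to 61.6 and 201 to 36.5 FPKM). The 4 that did not pass were Tnf (21.7 and 21.9 FPKM), Icam1, Ccl8 and Csf1. Of 6 tested neutrophil and granulocyte genes, 5 rose and 1 fell, also adjusted over the list alone (median log2 change 3.45, camera adjusted p = 0.00213; adjusted p = 0.169 with an estimated correlation). Lcn2, also an inflammatory factor, and Mmp8, a collagenase stored in neutrophil granules, rose to 207 and 84.8 ± 2.41 FPKM. Camp, a granule peptide, went from 0.717 ± 0.332 to 14 ± 1.7 FPKM, and S100a8, a calcium-binding protein abundant in neutrophils, from 2.76 ± 1.25 to 48.6 ± 8.85 FPKM. The member that fell was the growth factor receptor gene Csf3r (log2 change -0.31). Of these 6 genes, 4 reached a mean of 1 FPKM in the shControl libraries. Without a filter on low values the median over 13 members was 0.66 (adjusted p = 0.000647, in a range of 0.000647 to 0.0239 over 17 alternatives). S100a9, a neutrophil gene of the list, was at 1.29 FPKM in shVdac replicate 1, below the 3.12 FPKM of shControl replicate 3, and at 14.4 and 10.3 FPKM in shVdac replicates 2 and 3. The haemoglobin genes of red cells were also listed at traces: Hba-a1 had means of 0.117 and 1.95 FPKM in the shControl libraries and those labelled shVdac, and Hbb-bs was at 0.37, 0.57 and 0 FPKM in the former and 0.16, 2.37 and 3.18 FPKM in the latter.

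Transcripts of macrophages were abundant under both labels and moved both ways. Lyz2, the lysozyme of macrophages and granulocytes, stood at 5555 ± 141 FPKM in the shControl libraries and 7203 ± 21.6 FPKM in the libraries labelled shVdac. All 19 tested macrophage and monocyte genes reached a mean of 1 FPKM in the shControl libraries. Between the labels 9 rose and 10 fell, also adjusted over the list alone, and the list was not called (median log2 change -0.24, camera adjusted p = 0.713). Adgre1, the surface marker F4/80, rose 3.43-fold to 539 ± 19.7 FPKM, Cd14, a receptor for bacterial lipopolysaccharide, 1.94-fold, and Itgam, the integrin CD11b, 2.01-fold. Mrc1, the mannose receptor, went from 79.8 ± 2.81 to 13.8 ± 0.562 FPKM. RNA with macrophage transcripts at these levels was part of each library in which the other gene groups were measured. Of 7 osteoclast genes, 2 rose and 3 fell, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.638). The gelatinase gene Mmp9 rose to 110 ± 5.34 FPKM from 0.593 ± 0.146 and Acp5, tartrate-resistant acid phosphatase, rose 6.68-fold to 113 ± 1.66 FPKM. Atp6v0d2, a subunit of the osteoclast proton pump, and Tnfrsf11a, the receptor RANK, fell (log2 changes -1.38 and -1.32). Of 8 endothelial genes, 1 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.0792; adjusted p = 0.438 with an estimated correlation). Cdh5, the cadherin of endothelial junctions, went from 8.96 ± 0.452 to 2.35 ± 0.202 FPKM, and Pecam1, Cldn5 and Esam fell as well. The endothelial list was called with median-ratio scaling (adjusted p = 0.0348) and without a filter on low values (0.00402), in a range of 0.00402 to 0.31 over 16 alternatives. The lymphocyte list had 1 tested member, Ighm, and the erythroid list none, so neither was tested.

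Genes of the bone and fat lineages were mostly lower in the libraries labelled shVdac. Macrophage transcripts were part of each library, so which cells gave these values cannot be told. Sp7, the transcription factor osterix that commits cells to bone, went from 22.1 ± 0.265 to 3.11 ± 0.137 FPKM (log2 change -2.49, SE 0.043, adjusted p = 1.88e-09). Runx2, which acts upstream of it, changed less, from 5.25 ± 0.399 to 4.13 ± 0.121 FPKM (log2 change -0.28, adjusted p = 0.00369). Of 17 osteoblast and bone matrix genes, 14 fell and 2 rose, also adjusted over the list alone (median log2 change -0.91, camera adjusted p = 0.000686; adjusted p = 0.151 with an estimated correlation). Without shControl replicate 1, 2 or 3 the median was -0.57, -0.60 and -0.55 over the 13, 12 and 13 members that then passed the filter, and -0.91, -0.93 and -0.91 with the same 17 members tested. With no filter on low values, which lets in members near 0, the osteoblast median over 23 members was -0.28 (camera adjusted p = 4.89e-05). Besides Sp7 and Bmp4, Omd, the bone proteoglycan osteomodulin, went from 7.53 ± 0.341 to 0.533 ± 0.0814 FPKM and Alpl, the alkaline phosphatase of mineralization, from 75.9 ± 1.18 to 39.8 ± 0.159 FPKM. The 2 that rose, Bglap2 and Phospho1, stayed below 2 FPKM on average. Pparg, the master regulator of fat cells, went from 23.7 ± 0.545 to 3.06 ± 0.366 FPKM (log2 change -2.61, SE 0.066, adjusted p = 1.3e-08). Of 18 adipocyte genes, 13 fell and 3 rose, also adjusted over the list alone (median log2 change -1.38, camera adjusted p = 0.0112; adjusted p = 0.151 with an estimated correlation). Lpl, Cebpa, a transcription factor of late fat differentiation, and Plin1, a coat protein of lipid droplets, fell, with Cebpa at 82.7 ± 3.54 and 19.6 ± 0.318 FPKM. Cebpb, which acts early in fat differentiation and in inflammation, rose 4.53-fold to 123 ± 2.58 FPKM. The adipocyte call was lost without shControl replicate 1, 2 or 3 (adjusted p = 0.131, 0.13 and 0.112), where 13 members passed the filter and the median was -0.62, -0.66 and -0.64, but not with the same 18 members tested (0.0126, 0.011 and 0.00921, with medians of -1.38, -1.33 and -1.44). It was also lost with genes of at least 5 FPKM only (0.0623), in a range of 0.000104 to 0.131 over 17 alternatives. All 5 tested chondrocyte genes fell, also adjusted over the list alone (median log2 change -0.87, camera adjusted p = 0.0217; adjusted p = 0.173 with an estimated correlation), led by Col2a1, Comp, Col11a1 and Col10a1, of which only Col11a1 exceeded 10 FPKM in the shControl mean. Without shControl replicate 1, 2 or 3, or with a minimum of 5 FPKM, too few members passed the filter for the list to be tested. With the same 5 members tested its adjusted p was 0.0147, 0.0206 and 0.0237 without these libraries. Without a filter on low values, which lets in members near 0, the chondrocyte median over 11 members was -0.14 (camera adjusted p = 0.0242).

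Stromal markers and genes of osteoclast support moved both ways in the libraries labelled shVdac, and neither list was called on the genes tested. Of 18 mesenchymal stromal markers, 11 rose and 6 fell, 2 and 5 of them at least 2-fold, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.207). Cxcl12, the chemokine that retains blood stem cells in the marrow, went from 617 ± 5.55 to 126 ± 1.51 FPKM, and Kitl, stem cell factor, from 51.7 ± 5.69 to 7.58 ± 0.195 FPKM. Alcam, an adhesion molecule, fell (log2 change -1.09), and Grem1, an antagonist of bone morphogenetic proteins, rose 2.94-fold. Of 13 genes of osteoclast support and Wnt signalling, 2 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.262). The 2 that rose were Tnfsf11, the osteoclast-inducing cytokine RANKL, 8.58-fold to 21.3 ± 0.973 FPKM, and Wnt5a, 4.09-fold to 17.6 ± 0.775 FPKM. Sfrp1 and Sfrp2, secreted modulators of Wnt signals, fell (log2 changes -1.62 and -2.41). Without a filter on low values this list was called (adjusted p = 0.0499, in a range of 0.0499 to 0.537 over 17 alternatives). Of 23 extracellular matrix genes, 12 rose and 9 fell, also adjusted over the list alone (median log2 change 0.13, camera adjusted p = 0.0383; adjusted p = 0.607 with an estimated correlation). Dcn, the proteoglycan decorin, rose 4.84-fold to 51.6 ± 0.902 FPKM, Plod2, a collagen cross-linking hydroxylase, 3.02-fold, the fibrillar collagen gene Col3a1 2.16-fold and Postn, periostin, 2.75-fold. The matrix call was lost without shControl replicate 1, 2 or 3 (adjusted p = 0.0898, 0.051 and 0.0562; 0.0565, 0.0291 and 0.0374 with the same genes tested), with genes of at least 5 FPKM only (0.0623) and with quantile normalization (0.566), under which the median log2 change was -0.07; the range was 0.0136 to 0.566 over 17 alternatives. Of 14 contractile and myofibroblast genes, 6 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.326). The growth factor genes Ccn2 and Ccn1 and the stress-response gene Ankrd1 rose (log2 changes 1.71, 0.69 and 2.22), and the myosin kinase gene Mylk fell (-1.42).

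Genes of cell division fell as a whole in the libraries labelled shVdac. All 40 cell cycle genes fell, also adjusted over the list alone, 39 of them at least 2-fold (median log2 change -2.90, camera adjusted p = 3.95e-19; adjusted p = 0.00603 with an estimated correlation). Without shControl replicate 1, 2 or 3 only 22 of them passed the filter, with medians of -2.52, -2.52 and -2.51. Ccnb2 and Ccna2, cyclins of mitosis and of DNA replication, went from 33.1 ± 0.736 to 0.427 ± 0.0416 FPKM and from 23.5 ± 0.474 to 0.557 ± 0.0416 FPKM. Top2a, a topoisomerase of dividing cells, went from 22.1 ± 0.856 to 0.547 ± 0.0306 FPKM and Mcm6, part of the replicative helicase, from 45.2 ± 0.868 to 5.18 ± 0.176 FPKM. Cdkn1a, the cell cycle inhibitor p21, rose 2.56-fold from 65.9 ± 0.786 to 168 ± 4.55 FPKM (log2 change 1.34, SE 0.03, adjusted p = 6.56e-09). Cdkn2a, which encodes the senescence-associated inhibitors p16 and p19, fell from 18.9 ± 1.18 to 8.44 ± 1.42 FPKM (log2 change -1.09, SE 0.11, adjusted p = 3.89e-05). Of 22 p53 targets and senescence genes, 12 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.0629; adjusted p = 0.21 with an estimated correlation). The death receptor gene Tnfrsf10b rose 2.89-fold, while the cell cycle inhibitor gene Cdkn2c and Sesn1, a stress-induced regulator of growth, fell (log2 changes -2.55 and -1.63). The p53 list was called without shVdac replicate 1 or 2 (adjusted p = 0.0428 and 0.044), without a filter on low values (0.0312), with values rescaled to TPM (0.0376) and with voom on recovered fragments (0.0324), in a range of 0.0312 to 0.17 over 17 alternatives. Of 20 apoptosis genes, 4 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.862). Birc5, survivin, also a gene of dividing cells, fell from 14.4 ± 0.374 to 0.47 ± 0.105 FPKM, and the pro-apoptotic Bid fell (log2 change -0.84). The survival gene Mcl1 and the pro-apoptotic Pmaip1 rose (log2 changes 0.56 and 0.59).

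Stress-response lists moved in different ways. Of 20 genes of the unfolded protein response of the endoplasmic reticulum, 15 fell and 1 rose, also adjusted over the list alone (median log2 change -0.25, camera adjusted p = 0.0115; adjusted p = 0.242 with an estimated correlation). With median-ratio scaling the median was -0.14 (adjusted p = 0.0346, in a range of 0.000111 to 0.0346 over 17 alternatives). Edem1 and Sel1l, which serve the degradation of misfolded proteins, and Sdf2l1 and Ero1b, which serve folding, fell by 0.82, 0.50, 0.98 and 0.82 on the log2 scale. Of 24 oxidative stress genes, 10 rose and 11 fell, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.207). Hmox1, the haem-degrading enzyme, rose 4.96-fold to 1150 ± 22.9 FPKM, the superoxide dismutase genes Sod2 and Sod3 rose 7.83-fold and 3.57-fold, and the peroxidase gene Prdx5 rose 4.31-fold. Of 25 genes of the integrated stress response, 9 rose and 13 fell (10 and 13 adjusted over the list alone; camera adjusted p = 0.836). Ddit4, an inhibitor of growth signalling, and Slc7a11, the cystine importer, rose 6.61-fold and 11.7-fold, while Pck2 and Psat1, enzymes of glucose and serine synthesis, fell (log2 changes -1.24 and -1.21). Of 25 genes of cholesterol and fatty acid synthesis, 17 fell and 2 rose (18 and 2 adjusted over the list alone), with a median log2 change of -0.45 (camera adjusted p = 0.0383; adjusted p = 0.369 with an estimated correlation). Hmgcs1, an enzyme of cholesterol synthesis, and Insig1, which restrains it, fell (log2 changes -0.86 and -0.64), and the desaturase gene Scd2 rose 2.06-fold. The cholesterol call was lost without shVdac replicate 2 (adjusted p = 0.0653, and 0.0524 with the same genes tested) and with genes of at least 5 FPKM only (0.0897), in a range of 0.00103 to 0.0897 over 17 alternatives. Of 16 immediate early genes, 6 rose and 7 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.371). Ier3 rose 13.5-fold to 233 ± 12.1 FPKM, Fosl1 and Junb, parts of the AP-1 transcription factor, rose as well (log2 changes 2.01 and 0.87), and Egr2 fell (-1.57). Of 54 cytosolic ribosomal protein genes, 5 rose and 29 fell, also adjusted over the list alone, with a median log2 change of -0.18 (camera adjusted p = 0.0554), which was -0.07 with median-ratio scaling (adjusted p = 0.179); the list had an adjusted p = 0.72 with an estimated correlation. Rpl3, Rpl35 and Rps4x were among those that fell, and this list was called under 8 of its 17 alternatives, among them without shControl replicate 2 (adjusted p = 0.00581), without shControl replicate 3 (0.0474) and without shVdac replicate 2 (0.0154), in a range of 0.000451 to 0.179. Ribosomal protein genes have many processed copies that may share their reads, and Rps2 was listed at only 3.59 FPKM in the shControl libraries, so values of this list are uncertain.

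**Figure D3:**
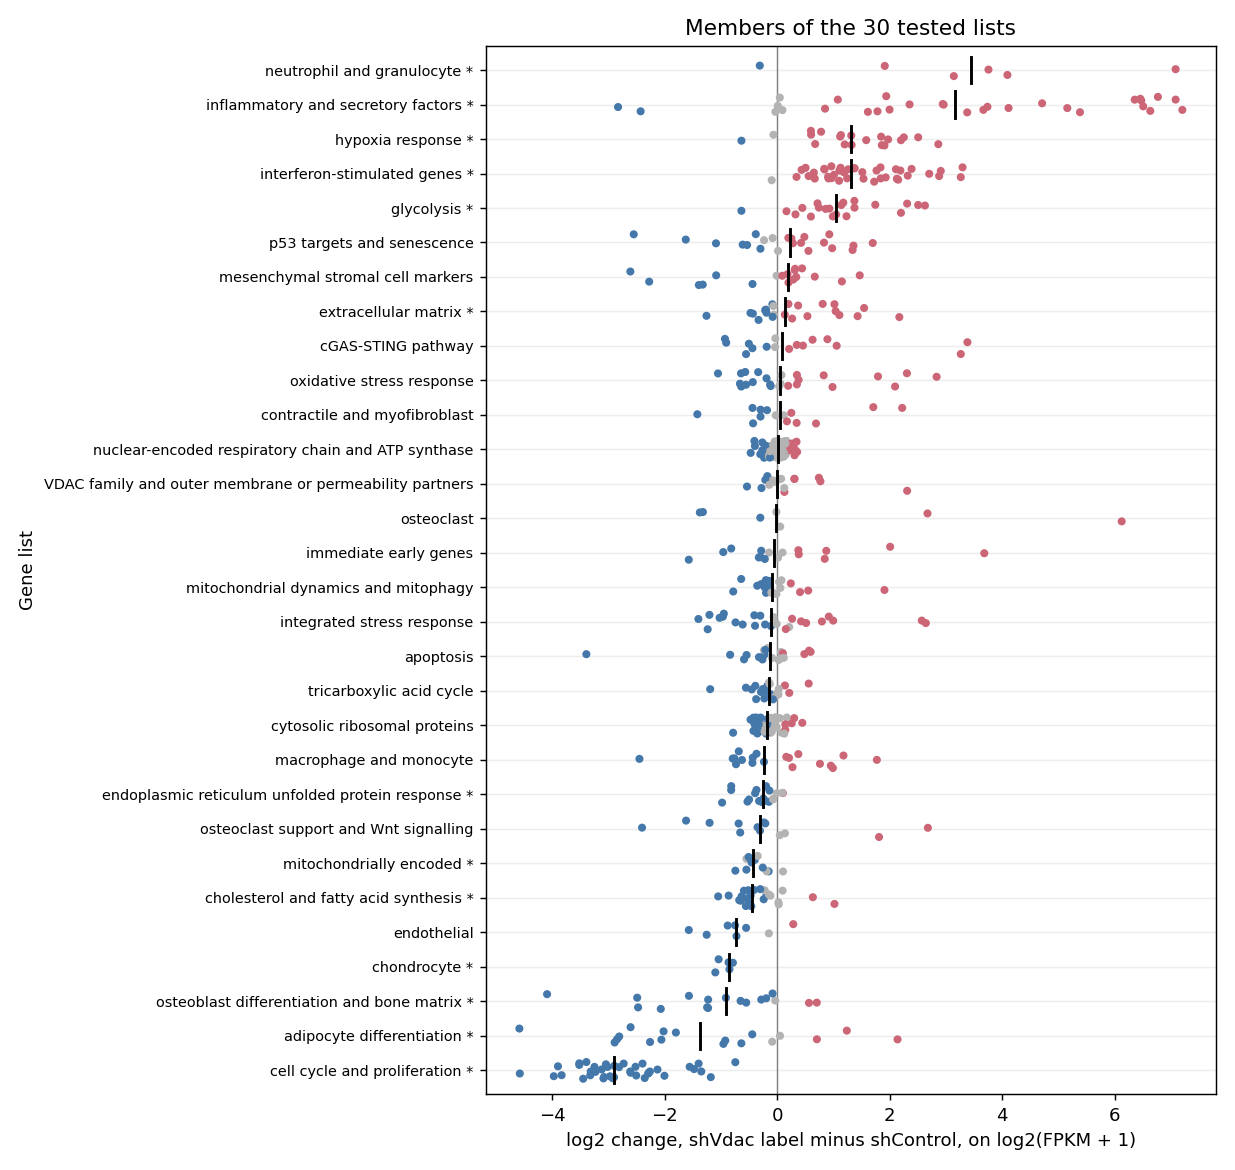
Each point is 1 tested gene of a list, placed by its log2 change on the x axis (red, higher and blue, lower in the libraries labelled shVdac at adjusted p under 0.05; grey, not past the test); black bars are list medians and asterisks mark the 13 lists called by camera. The cell cycle list lies wholly below 0, with a median of -2.90, and the inflammatory list has a median of 3.17.

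Of the 30 lists tested, camera called 13, with 6 up and 7 down. Cell cycle, interferon-stimulated, inflammatory, glycolysis and hypoxia genes, 5 lists, held with an estimated correlation. Camera compares a list with all other genes, while the median and the mean are of the log2 changes of its members alone. The direction of camera, the median and the mean were not of 1 sign for some lists, none of which was called. These were the stromal marker, macrophage, osteoclast, VDAC partner, respiratory chain, mitochondrial dynamics, integrated stress and immediate early lists. Libraries of the same label differed by a CV of only 0.957% to 3.92% beyond counting error among well covered genes. These were the 1248 to 1319 genes with at least 5000 fragments summed over a pair. Whether each library came from its own mouse or culture is not stated for each library. The p-values measure only the spread between these libraries, which may be technical. With 3 libraries per label and a targeted transcript that was not lower, the comparison is between labels. Members named besides the 4 with the smallest p of their list, namely Slc2a3, Gapdh, Pkm, Ndrg1, mt-Co1, mt-Co3, Gbp2, Ifnb1, Igfbp4, Igfbp5, Tnf, Icam1, Ccl8, Csf1, Csf3r, S100a9, Hba-a1, Hbb-bs, Lyz2, Bglap2, Phospho1 and Rps2, were chosen after their values were seen.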

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

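The alternatives here were planned before the data were examined, apart from voom on recovered fragments and the fits without 1 library on the same genes, which were chosen after the result was seen. Vdac1 was higher in the libraries labelled shVdac, at an adjusted p under 0.05, under each alternative: its log2 change ran from 0.09 with each library rescaled to the same sum (TPM) to 0.27 with median-ratio scaling, and from 0.13 to 0.18 when 1 library was left out. The rule named 133 other genes. Apart from those always named, they were picked for large changes or small p in the main fit of the same data. That they kept their calls was therefore largely assured, and it does not speak for calls in general. A gene that did not pass the filter under an alternative gave no value there. Of the values these genes had under the alternatives, 2989 of 2991 kept their direction and side of the threshold. The exceptions were Vdac2 and Vdac3, at -0.06 and -0.07 (adjusted p = 0.156 and 0.177) with median-ratio scaling, which moves the log2 change of a typical gene by 0.1.

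The number of genes changed, 7877, ran from 5564 with a minimum of 5 FPKM, which tests fewer genes, to 8546 without a filter, and was 6437 at an adjusted p of 0.01. Without 1 library, 6670 to 7397 genes changed, 2438 to 2712 of them higher and 4041 to 4875 lower, and 1072 to 1240 changed at least 2-fold. Part of this is the filter, which removes genes expressed under 1 label when a library of it is left out: with the same 12491 genes tested, 7230 to 7641 changed, and 1358 to 1366 at least 2-fold. Of the 7862 genes called with median-ratio scaling, 6740 were called in the same direction without it, and of the 7983 called by voom, 7524. Higher genes made up 50.9% of calls with median-ratio scaling, 48.4% with quantile normalization and 29.5% with each library rescaled to the same sum (TPM). The number changed at least 2-fold, 1349, ran from 967 with a minimum of 5 FPKM to 1880 with voom.

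The number of lists called, 13, was 5 with an estimated correlation and 29 with fry, which asks another question, since it does not compare a list with other genes. The cause of the fall to 5 was not tested, but a higher gene correlation does not account for all of it. The adipocyte, chondrocyte and mitochondrially encoded lists lost their call with estimates of -0.0155, -0.1023 and -0.0567, below the fixed 0.01. The interferon list, at -0.0126, went from a camera adjusted p of 2.61e-22 to 0.00603. A call lost or weakened under this setting is therefore no evidence by itself that the members of a list are correlated. Other lists that lost their call had estimates from 0.0454 to 0.2388. The number called ran from 9 with a minimum of 5 FPKM to 18 without a filter, and from 10 to 14 without 1 library, or 11 to 14 with the same genes tested. Without a filter, which lets in members near 0, the median log2 change was 0.66 for the neutrophil list, -0.28 for osteoblast genes and -0.14 for chondrocyte genes, and with median-ratio scaling it was -0.14 for the unfolded protein response. In lists that were not called, the direction of camera turned under some alternatives, in 7 of 17 for mitochondrial dynamics, 4 of 17 for the integrated stress response, 3 of 17 for osteoclast genes, 2 of 17 for macrophage genes and 1 of 17 for contractile genes, and for the respiratory chain without shVdac replicate 2 on the same genes (adjusted p = 0.927).

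The numbers in the titles did not pair the libraries: with group means removed, same-number libraries had correlations of -0.0073, -0.0437 and -0.0576 across genes. With the number as a replicate block, 7490 genes changed, 2718 higher and 4772 lower, 1348 at least 2-fold, with 13 lists called and a Vdac1 log2 change of 0.16 (limma adjusted p = 0.0276). What depth limits was not tested by varying it.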

Other observations

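Tests of exchanged labels, of another VDAC gene, of macrophages, of neutrophils and of the closeness of replicates were chosen after the result was seen; those of Vdac1 copies and of other splits were planned. Genes named in this and the next paragraph were chosen after their values were seen. Some genes outside the lists were far higher in the libraries labelled shVdac, although the transcript of the targeted gene goes against that label. Nos2, the inducible nitric oxide synthase, went from 0.12 ± 0.0529 to 71.6 ± 4.45 FPKM, and Acod1, which makes itaconate, from 6.03 ± 0.0981 to 274 ± 6.33 FPKM. The formyl peptide receptor genes Fpr1 and Fpr2 rose to 307 ± 3.32 and 224 ± 5.62 FPKM, and Cd38 and Cd274, the latter the checkpoint ligand PD-L1, to 111 ± 1.33 and 74.5 ± 1.76 FPKM. Others fell in the libraries labelled shVdac: Cd5l, a secreted protein of macrophages, from 174 ± 5.97 to 14.1 ± 0.35 FPKM, Igf1, a growth factor, from 66.2 ± 0.813 to 8.3 ± 0.31 FPKM, and Slc40a1, the iron exporter ferroportin, from 21.8 ± 0.656 to 3.3 ± 0.209 FPKM.

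In the libraries labelled shVdac, Timp1, an inhibitor of matrix proteases, rose from 193 ± 3.75 to 1834 ± 89.4 FPKM, Inhba, a subunit of activin, from 10.9 ± 0.503 to 141 ± 2.07 FPKM, and Has2, a hyaluronan synthase, from 2.9 ± 0.0764 to 34.2 ± 0.917 FPKM. Mgp, the matrix Gla protein that inhibits calcification, fell from 23.6 ± 3.1 to 1.09 ± 0.0551 FPKM, Aspn, the proteoglycan asporin, from 54.0 ± 5.08 to 6.07 ± 0.0473 FPKM, and Fgfr2, a growth factor receptor, from 19.3 ± 0.206 to 1.41 ± 0.0666 FPKM. Transcripts of other blood cells were seen at traces that differed between libraries of a label. S100a9, abundant in neutrophils, was at 0.22, 0.48 and 3.12 FPKM in the shControl libraries and at 1.29, 14.4 and 10.3 FPKM in the libraries labelled shVdac, and the haemoglobin gene Hbb-bs was at 0.37, 0.57 and 0, and at 0.16, 2.37 and 3.18 FPKM.

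Vdac1 was not lower in the libraries labelled shVdac. An exchange of the labels could place a knockdown of the transcript in the libraries labelled shControl, but their Vdac1 level was 0.897 of that in the others (spread 0.0417). A knockdown of a transcript was taken, after the ratios were seen, to need a ratio under 0.7. The ratio of Vdac2, shVdac over shControl, was 0.884, above this limit, which opposes a knockdown of its transcript. The ratio of Vdac3 was 0.879 (spread 0.0402), but its values are uncertain because of its pseudogene, so this ratio cannot decide. Reads from processed copies could fill the gene. The 2 listed genes with a transcript at least 90% identical to Vdac1 summed to 0.0044 of its level. Reads of copies counted as Vdac1 would be missing from the values of the copies, and copies outside the annotation were not searched. This ratio therefore cannot decide. A hairpin that lowers the protein and not the transcript stays open, and ratios of transcripts cannot oppose it. Reads from processed copies, a hairpin that lost its effect by the time of sampling, and libraries from other samples than the labels say also stay open. No value in these data tests any of these. Each library also held macrophage transcripts, so the Vdac1 level of the stromal cells alone was not measured. The design gives no biological explanation that was tested.

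Inflammatory and secretory factors were higher in the libraries labelled shVdac. If a larger share of macrophages, unchanged in state, were the only source, the macrophage list would rise by about the inflammatory median, 3.17. The median of the macrophage list was -0.24 with an SD of 0.96. Without shVdac replicate 1, 2 or 3 the inflammatory median was 1.92, 1.97 and 1.92, over the 21 members that then passed the filter, above that of the macrophage list by more than this SD. All 19 tested macrophage genes were expressed in the shControl libraries, with 0 held by another list. Lyz2 already stood at 5555 FPKM there, which left little room for so large a rise in share. The test could therefore hardly come out otherwise. A smaller rise in share, or one joined to a change of state, was not tested. Of the 19 genes 9 rose and 10 fell, among them Adgre1 and Mrc1 (log2 changes 1.77 and -2.45). Neutrophils bring S100a8 and S100a9 in abundance, but these summed to 57.3 FPKM in the libraries labelled shVdac, 0.0067 of the 8511 FPKM of the 24 inflammatory factors that rose. This speaks only to the summed level of factors picked because they rose in these same libraries, where Saa3 alone stood at 2675 FPKM. Whether neutrophils brought part of single factors, such as Lcn2 or Il1b, it cannot tell. A change of state in the macrophages or stromal cells already present, through the hairpin, its delivery or the culture, may be the source and was not tested, and delivery of the hairpin is not described in the sources used here.

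Libraries of 1 label differed little. Whether the 3 libraries of a label come from 1 culture or RNA cannot be told apart from separate mice kept alike: the lowest ratio of the variance between libraries of a label to that of counting was 1.55 over 6 pairs and the highest 2.45, between the values set for 1 source and for separate ones, while pairs across labels had ratios of 23.4 to 25.2. Among well covered genes the ratio within a label was 1.74 to 8.26. Among the libraries labelled shVdac, replicate 2 stood furthest apart. Replicates 1 and 3 had a ratio of 1.55, and 1.74 among well covered genes, against 2.41 and 8.24 to 8.26 with replicate 2. Replicate 2 also stood furthest apart among the shControl libraries. There replicates 1 and 3 had a ratio of 1.65, and 2.66 among well covered genes. With shControl replicate 2 the ratios were 2.45 and 2.16, and 7.9 and 5.1 among well covered genes. Some transcripts of blood cells set shVdac replicate 1 apart from replicates 2 and 3 instead: S100a9 was at 1.29, 14.4 and 10.3 FPKM, Ngp at 0.5, 5.87 and 3.95, Ltf at 0.14, 1.21 and 0.91, Hba-a1 at 0.53, 2.32 and 3.01, and Hbb-bs at 0.16, 2.37 and 3.18 FPKM. Others did not: S100a8 was at 41.0, 58.3 and 46.6, Camp at 12.3, 15.7 and 14.1, and Csf3r at 8.79, 7.98 and 9.51 FPKM. The genes from S100a9 to Hbb-bs argue against 1 RNA for the 3 libraries labelled shVdac. They are low, were chosen after their values were seen, and other blood cell genes do not share their pattern. They were therefore not used to exclude 1 RNA. If the libraries of a label share a source, the difference between labels could also be one between 2 cultures.

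The 6 libraries have 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 7877 genes changed, 1349 at least 2-fold and 13 lists, and in each case 1 of the 10 splits, the real one, gave as many. The highest of the other splits was 0 genes changed and 0 at least 2-fold by limma, with 67 to 199 genes at an unadjusted p under 0.05 in those splits, and 11 lists. Each of those splits mixes the labels, which puts the difference between labels into the spread within groups. That no genes were called in them was therefore assured. The splits also keep part of that difference, so neither their genes nor their lists show what is seen without one.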
